A study of Mus musculus with 2 samples.

How the data were processed

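The data are filtered single-cell matrices of UMI counts from 2 libraries of transferred NK cells sorted from mouse lungs, 1 labelled D21PBSpi and 1 labelled D21SPNpi. Per the file headers, the deposited counts were written by Cell Ranger 4.0.0, and per the submitters' processing notes the genome build was mm10. The values are whole UMI counts per gene and barcode, with no normalization. Per the labels' protocols, cells were lysed in 0.2% Triton, polyadenylated RNA was reverse transcribed with a primer holding a UMI and a cell barcode, and cDNA was amplified by in vitro transcription. Adaptors with a batch barcode were ligated, 16 PCR cycles followed, and sequencing used a NextSeq 500 with a 75-cycle kit. Barcodes of 16 bases and the file headers belong to a droplet workflow, which that protocol text does not describe, and which of them applies is not given in the sources used here. The annotation release behind the 32285 genes is not given in the sources used here either. The smallest barcode in each library had 500 UMIs.

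Each file was assigned to its sample by the series record and each sample to its group by its title. Words in the file names give the opposite assignment, so groups are named by label throughout. With 1 library per group, cells were not used as replicates. Counts over cells were summed per library, and ratios of CPM carry exact conditional (Clopper-Pearson) 95% intervals. CPM of a sum has an exact Poisson interval and shares have exact Clopper-Pearson intervals, and all of these cover counting error only. A gene with 0 counts in 1 library was put at a floor of 3 counts over the group.

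Cells were kept with at least 500 genes and under 10% mitochondrial UMIs. This left out 387 barcodes (12.1%) labelled D21PBSpi and 213 (7.30%) labelled D21SPNpi. Scrublet, run within each library through scanpy 1.11.5, called 24 of 5529 cells (0.434%) as doublets. Under 0.5% of over 5000 cells is read as a caller that has not worked, so doublets may remain among the cells, and an alternative without cells over 2.5 times the median UMIs was added. Both libraries were log-normalised to 10000 and clustered together without integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6). Clusters were named from markers of 18 cell types fixed before the data were examined. Leading genes had to have a UMI in at least 10% of a cluster's cells, a condition set after the data were seen because single stray cells otherwise supplied them. A cluster whose cells had a median under 1 / 3 of their own library's UMIs, with no marker of its best type among its 10 leading genes, stayed unnamed, as would a cluster with fewer than 3 markers detected or with more leading markers of another type.

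Gene lists, 10 primary and 11 secondary, were fixed before the data were examined. Each list value is the median log2 CPM ratio of members with at least 20 UMIs over both libraries, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Members count as higher at a ratio of at least 1.25 and lower at 0.8 or less. The list of sex-linked transcripts had 2 measured members, Xist (ratio 0.851) and Tsix (0.661), whose reads overlap on opposite strands, so no percentile was computed for it. Shares of cells with a UMI were computed after thinning each cell to 2500 UMIs, the 10th percentile in the shallower library rounded down to a multiple of 100. Named genes follow a rule fixed in advance. Its first part takes, among genes with at least 100 UMIs and without mitochondrial, ribosomal protein and numbered gene models, the 12 highest and 12 lowest ratios ranked by the interval bound nearest to 1. Its other parts take up to 2 highest and 2 lowest members per list, 9 genes named in every case (Gzmb, Prf1, Gzma, Ifng, Ncr1, Klrb1c, Klrg1, Cd69 and Mki67), and cell type markers in the account of contamination. Some genes that the rule selects are not reported here. Isg15 was among the genes fixed for shares. Coordinates come from GENCODE M21 on mm10, matched on the gene identifier for 32158 of 32285 genes.

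The ratio step was tested on simulated data for this comparison. Counts for 11180 genes were drawn from the real means and library sizes in 20 simulations with 200 altered genes each. These genes had at least 20 UMIs over all filtered cells, before called doublets and unnamed cells were left out. The NK-like cells had 11131 such genes. Median recovered folds were 0.250, 0.495, 1.50 and 2.98 for simulated folds of 0.25, 0.5, 1.5 and 3, and the intervals held the true ratio for 95.8%, 95.8%, 95.3% and 95.7% of those genes. Each gene was an independent Poisson draw per library, the model behind the intervals, so coverage near 95% was built in. Variation between cells or animals and genes that vary together were not simulated, so the simulation checks the computation only. Of 20 random lists of 30 genes, 19 fell between percentiles 5 and 95, and a list lowered 1.5-fold fell below every random list.

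Alternatives were TMM scaling with edgeR 4.0.16, a total without mitochondrial and ribosomal protein genes, equal weight per cell, other cell sets and filters, other clustering resolutions, other UMI minimums and other thinning depths. Tools were Python 3.11.15, anndata 0.12.19, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and R 4.3.3.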

Results

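Single-cell RNA was measured in mouse natural killer (NK) cells, innate lymphocytes that kill target cells and release interferon-gamma. Donor C57BL/6J mice aged 7 to 12 weeks received either saline or the bacterium Streptococcus pneumoniae. After 21 days their spleen NK cells were purified and transferred into naive congenic recipients, which carry a different leukocyte marker so that donor cells can be told apart. The recipients were infected 24 h after the transfer, and the donor cells were sorted from their lungs 40 h after that infection. The series design calls the cells of saline-treated donors naive (D21PBSpi) and those of pre-infected donors memory (D21SPNpi), and compares them after the second infection. Each group has 1 library, so no difference has a replicate check and no test between groups was made. Intervals are 95% exact intervals and cover counting error only, except where a bootstrap is named.

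The direction of every comparison rests on the sample labels. Words in the deposited file names assign the libraries the opposite way, naming as memory cells those whose sample is labelled D21PBSpi, and nothing in the values can settle which is right. The libraries are therefore written as labelled D21PBSpi and labelled D21SPNpi, and every direction would turn around if the file names were right.

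The library labelled D21PBSpi held 3210 barcodes with 18737053 UMIs, and the library labelled D21SPNpi held 2919 barcodes with 14229113 UMIs. A UMI marks 1 captured RNA molecule. Per barcode the medians were 5408 UMIs and 1884 genes in the former, and 4680 UMIs and 1821 genes in the latter. After filtering on genes and mitochondrial UMIs and removal of called doublets, 2820 and 2685 cells were kept.

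Nearly all kept cells carried NK cell transcripts. Every one of the 6 clusters detected all 13 NK markers, among them the activating receptors Ncr1 and Klrb1c (NK1.1) and the killing genes Gzma, Prf1 and Nkg7, and in no cluster did the markers of another type come near them. Cd4 and Cd8a, the coreceptor genes of T cells, had 0 UMIs in both libraries, while genes of the T cell receptor complex were low but not all absent. Cd3e had 2 UMIs in the NK-like cells labelled D21PBSpi and 0 in those labelled D21SPNpi, Cd3d had 132 and 83, and Cd3g had 101 and 63. At least 5 UMIs of T cell markers were held by 336 and 273 NK-like cells. The myeloid gene Lyz2 and the alveolar epithelial gene Sftpc also had 0 UMIs in both libraries. The hemoglobin gene Hbb-bs had 4880 UMIs over all barcodes labelled D21PBSpi, 17 of them in NK-like cells, and 1 UMI in the library labelled D21SPNpi. The neutrophil gene S100a8 had 4 and 27 UMIs over all barcodes. Trbc2, a T cell receptor constant gene that NK cells also transcribe, was the most abundant T cell marker, at 181 CPM (counts of the gene per 1e6 UMIs) and 182 CPM. Few NK-like cells held at least 20 UMIs of another type's markers. In the library labelled D21PBSpi these were 4 cells for T cells, 2 for epithelium, 1 for gamma-delta T cells and 1 for monocytes or macrophages. In the library labelled D21SPNpi they were 2 for ILC1, 2 for B cells, and 1 each for ILC2, neutrophils, dendritic cells and fibroblasts. The female transcript Xist was present in both libraries and the Y-linked genes Ddx3y and Eif2s3y had 0 UMIs in both, while Kdm5d and Uty had 1 UMI in each.

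The share of kept cells called NK-like was 88.2% (2488 of 2820 cells) in the library labelled D21PBSpi and 99.3% (2667 of 2685) in the library labelled D21SPNpi. The remainder was a single cluster of low-UMI cells, left unnamed by the naming rule although it detected the NK markers, with 332 cells of the former and 18 of the latter. Its median was 1566 UMIs per cell, so the rule on low UMIs sets this share, and it was 100% in both libraries at a coarser clustering. A gate in place of clusters asked for a UMI of Ncr1 or Klrb1c and for no UMI of Cd3d, Cd3e, Cd3g, Cd79a or Lyz2. It gave the opposite order, 91.0% and 86.7%. The gate used unthinned cells, so its shares also depend on UMIs per cell. NK-like cells had a median of 6074.5 UMIs in the library labelled D21PBSpi and 4810 in the library labelled D21SPNpi.

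The libraries sat largely in different NK-like clusters. Cells labelled D21PBSpi lay mostly in clusters 0 (1206 cells) and 1 (802 cells). Cells labelled D21SPNpi lay mostly in cluster 5 (1759 cells), then in cluster 3 (546 cells) and cluster 4 (302 cells). Only cluster 3 held at least 100 cells of each, with 462 and 546. A cluster made up mostly of 1 library may be that library and not a cell state, so cluster sizes are not compared here. All values that follow sum the UMIs of the NK-like cells of each library. Over the 11131 genes with at least 20 UMIs the median log2 ratio of CPM, labelled D21SPNpi over labelled D21PBSpi, was 0.23 and not 0, so list medians are also given relative to that value. That value is not matched on expression. Random lists matched on expression had a median of -0.04 for oxidative phosphorylation and 0.27 for the G2 and M phase. A value relative to all genes and a percentile can therefore point different ways. Members of a list are counted as lower at a ratio of 0.8 or less, as higher at the inverse of 0.8 or more, and as neither in between. Members called highest or lowest are so among those with at least 100 UMIs over both libraries.

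The genes furthest apart between the libraries included several that NK cells use. By the labels, Cd7, a receptor of lymphocytes, was 20-fold higher (interval 16.2 to 25) in the library labelled D21SPNpi, at 105 CPM against 5.25 CPM. Within that library it stood at 158 CPM in cluster 5, but at 9.92 CPM in cluster 4 and 3.77 CPM in cluster 3. The protease gene Cma1 (chymase) was 9.71-fold higher (8.91 to 10.6), at 330 CPM against 34.0 CPM. The adhesion gene Mcam was 13.3-fold higher (9.38 to 19.4), the prostaglandin synthase gene Ptgs1 66.7-fold (18.0 to 558), and Rab27b, a regulator of vesicle secretion, 13.0-fold (7.34 to 25). Phactr3 was 11-fold higher, Frat2 10.3-fold and the histone gene Hist1h2ap, whose reads can be shared with near-identical copies, 8.99-fold. The metallothionein gene Mt1 was 55.0-fold higher with 1083 UMIs against 25, and 52.5% of the 1083 lay in 1 cell. Within the library labelled D21SPNpi Mt1 stood at only 1.67 CPM in cluster 5, but at 114 CPM in cluster 3 and 582 CPM in cluster 4. Cluster 3 labelled D21PBSpi had 1.37 CPM. Without the 3 cells that held epithelial or fibroblast markers, a step chosen after the values were seen, Mt1 was 26.1-fold higher. Mt2 had 490 UMIs against 0, which is 207-fold higher with the 0 put at a floor of 3 counts (interval from 168 upward). At that floor it was 39.4-fold higher without those cells and 29.6-fold with the gate in place of clusters. Cluster 5 labelled D21SPNpi had 0.222 CPM of Mt2, against 25.2 CPM in cluster 3 and 336 CPM in cluster 4. Saa3 and Timp1 also ranked among the 12 highest, but 98.0% of Saa3 UMIs and 99.4% of Timp1 UMIs came from 1 cell.

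Genes at the other end included interferon targets and cytokines. By the labels, the prostaglandin receptor gene Ptger3 was lower in the library labelled D21SPNpi at a ratio of 0.0444 (0.0142 to 0.106), as was the interferon-induced Ifitm1 at 0.0671 (0.0362 to 0.115). Il10, which encodes an anti-inflammatory cytokine, stood at 6.23 CPM against 32.6 CPM, a ratio of 0.191 (0.151 to 0.240). The interferon-induced genes Ifi27l2a, Phf11a, Bst2 (tetherin) and Ifi44 had ratios of 0.170, 0.232, 0.238 and 0.244. Xcl1, a chemokine that attracts dendritic cells, stood at 598 CPM against 2038 CPM, a ratio of 0.293 (0.286 to 0.3). Olfr1369-ps1 and AW011738 were lower as well, at 0.217 and 0.268. Scgb1a1 and Scgb3a2, secretoglobins of airway epithelium, completed the 12 lowest. Of their UMIs labelled D21PBSpi, 71.5% and 84.5% came from a single cell.

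In mm10 the annotation places Cd7 on chromosome 11 from 121036747 to 121039418, Cma1 on chromosome 14 from 55941451 to 55944675, and Gzmb on the same chromosome from 56258838 to 56262260. Bst2 lies on chromosome 8 from 71534255 to 71537456, Il10 on chromosome 1 from 131019845 to 131024974, Xcl1 on chromosome 1 from 164931644 to 164935527, and Ccl5 on chromosome 11 from 83525778 to 83530518. The UMIs are summed over the whole gene.

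Summed over NK-like cells, the main killing genes were lower in the library labelled D21SPNpi by the labels. The cytotoxic list as a whole was not shifted one way. Gzmb (granzyme B) stood at 9193 CPM against 12644 CPM, a ratio of 0.727 (0.722 to 0.732). Within the library labelled D21SPNpi Gzmb stood at 2068 CPM in cluster 5, but at 21635 CPM in cluster 3 and 24666 CPM in cluster 4. Clusters 0, 1 and 3 labelled D21PBSpi had 12614, 9210 and 18936 CPM, so the lower sum came from cluster 5. Prf1 (perforin) stood at 1756 CPM against 2437 CPM (ratio 0.721, 0.709 to 0.732) and Gzma (granzyme A) at 13609 CPM against 17701 CPM (ratio 0.769, 0.764 to 0.773). In clusters 5, 3 and 4 labelled D21SPNpi Prf1 stood at 1871, 1573 and 1102 CPM and Gzma at 13376, 13207 and 14900 CPM. In clusters 0, 1 and 3 labelled D21PBSpi Prf1 stood at 3249, 1985 and 1778 CPM and Gzma at 22841, 15381 and 12419 CPM. The lysosomal membrane gene Lamp1 was higher at 1.78 (1.64 to 1.93). Of the 21 cytotoxic effectors measured, 6 were higher and 5 lower, against 4 and 8 under TMM scaling. Their median log2 ratio was 0.06 (-0.16 relative to all genes, and -0.18 under TMM), at percentile 61.3 of 10000 random lists matched on expression.

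Per cell, Gzmb differed more than its pooled level. After thinning each cell to 2500 UMIs, which left out 89 cells labelled D21PBSpi and 264 labelled D21SPNpi, the median was 26 Gzmb UMIs in the library labelled D21PBSpi (quartiles 17 and 41) and 6 in the library labelled D21SPNpi (quartiles 3 and 26). The 90th percentiles were close, at 66 and 71 UMIs. Ifng, the gene of interferon-gamma, had nearly equal pooled levels of 6033 CPM and 6460 CPM (ratio 1.07, 1.06 to 1.08, and 0.901 under TMM). Its median was 6 UMIs per cell in the library labelled D21PBSpi and 1 in the library labelled D21SPNpi, with 90th percentiles of 34.2 and 38.8. An Ifng UMI was found in 92.7% (91.6% to 93.7%) and 67.4% (65.5% to 69.3%) of thinned cells, or 98.2% and 80.4% unthinned. At this depth the share was thus lower in the library labelled D21SPNpi, though its pooled CPM was nearly equal. No cell type that should lack these genes was present to measure free RNA, so shares of cells with a UMI can include it.

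**Figure D1:**
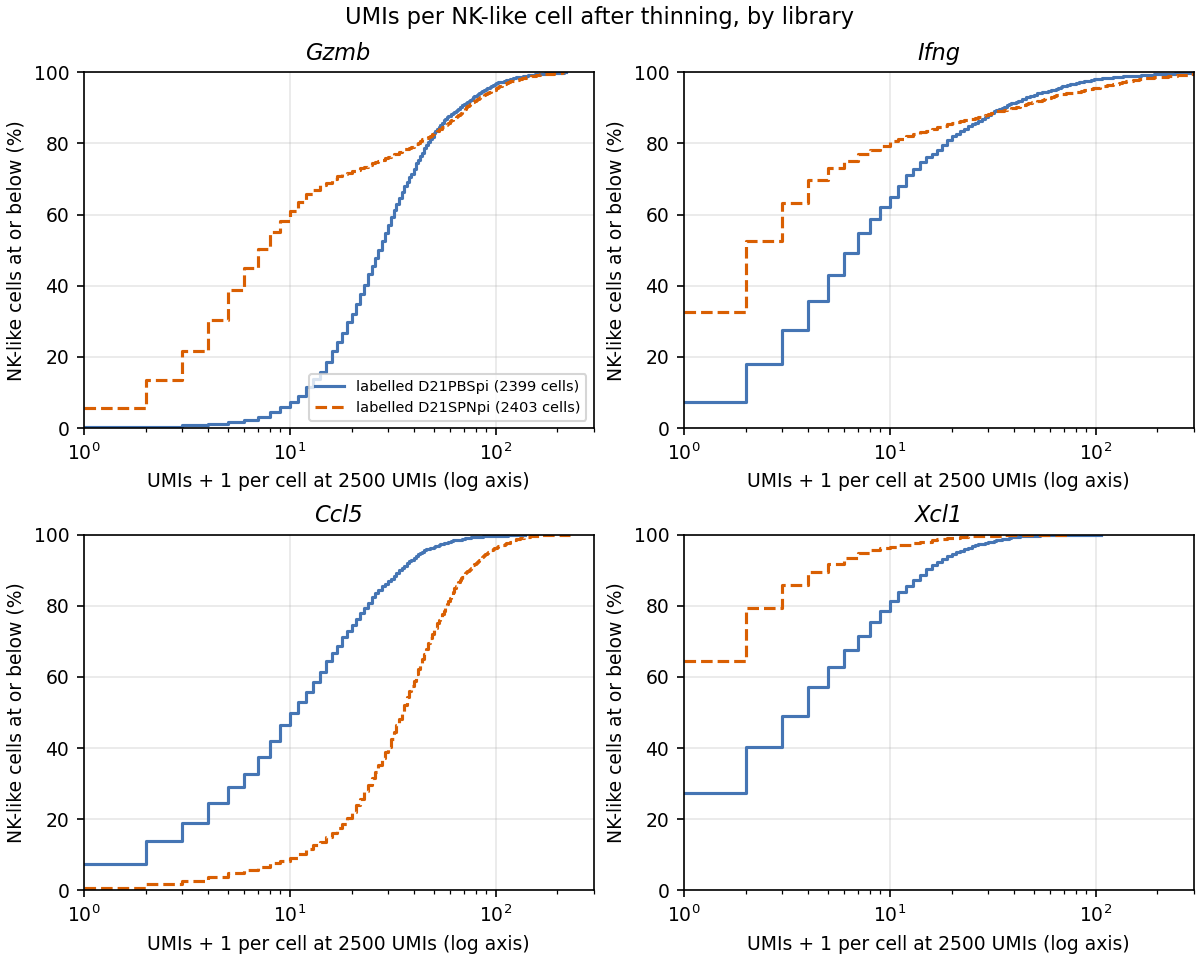
Cumulative percent of NK-like cells (vertical axis) at or below a number of UMIs plus 1 (horizontal log axis) for Gzmb, Ifng, Ccl5 and Xcl1, with each cell thinned to 2500 UMIs. The solid line is the library labelled D21PBSpi (2399 cells) and the dashed line the library labelled D21SPNpi (2403 cells). Median Gzmb is 26 against 6 UMIs and median Ccl5 10 against 35, while the Gzmb and Ifng curves cross near their upper ends.

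Chemokine and cytokine genes went both ways between the libraries, as labelled. Ccl5, which attracts T cells and other leukocytes, was 2.93-fold higher (2.90 to 2.95) in the library labelled D21SPNpi, at 14176 CPM against 4844 CPM, and its thinned median was 35 UMIs against 10. Ltb (lymphotoxin beta) was 4.09-fold higher (2.91 to 5.85). Il10, Csf2 (GM-CSF, ratio 0.292, 0.170 to 0.479) and Xcl1 were lower, and an Xcl1 UMI was found in 35.4% of thinned cells (33.5% to 37.4%) against 72.7% (70.8% to 74.4%), or 42.1% against 81.6% unthinned. Of 18 measured members 5 were higher and 8 lower, or 4 and 11 under TMM. The median log2 ratio was -0.30 (-0.53 relative to all genes), at percentile 0.09 of the random lists. The summed CPM of the list went the other way, 29101 against 22347, but mainly through Ccl5, at 14176 CPM against 4844 CPM.

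Interferon-stimulated genes were lower as a group in the library labelled D21SPNpi, by the labels. Of the 44 type I interferon-stimulated genes measured, 40 were lower and 0 higher. The median log2 ratio was -0.85 (-1.08 relative to all genes), below all 10000 random lists, and the summed level was 2596 CPM against 5445 CPM. The size depends on the cells used: among NK-like cells of 4500 to 6500 UMIs the median was -1.71. It also differs between the clusters of the library labelled D21SPNpi, with Bst2 at 41.7 CPM and Gbp6, an interferon-gamma target, at 6.00 CPM in cluster 5, but at 190 CPM and 98.3 CPM in cluster 4. Cluster 0 of the library labelled D21PBSpi had 664 CPM and 92.8 CPM. Ifi27l2a and Bst2 were the lowest members with at least 100 UMIs, and the transcription factor genes Irf9 (0.851, 0.776 to 0.932) and Stat2 (1.04, 0.923 to 1.17) were the highest of these. A UMI of Isg15, a ubiquitin-like interferon target, was found in 22.8% of thinned cells (21.1% to 24.5%) against 61.1% (59.1% to 63.1%), or 31.3% against 80.7% unthinned. Of the 33 genes of the interferon-gamma response and antigen presentation, 24 were lower and 0 higher, with a median of -0.49 (-0.71 relative to all genes), again below every random list. Socs1, a brake on cytokine signalling, stood at 107 CPM against 259 CPM (ratio 0.412, 0.388 to 0.437) and the GTPase gene Gbp6 had a ratio of 0.391 (0.342 to 0.446). The class I gene H2-D1 (1.18, 1.16 to 1.19) and Irf8 (1.15, 1.14 to 1.17) were the highest members. Mx1 and Mx2 were not among the gene symbols of the files.

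**Figure D2:**
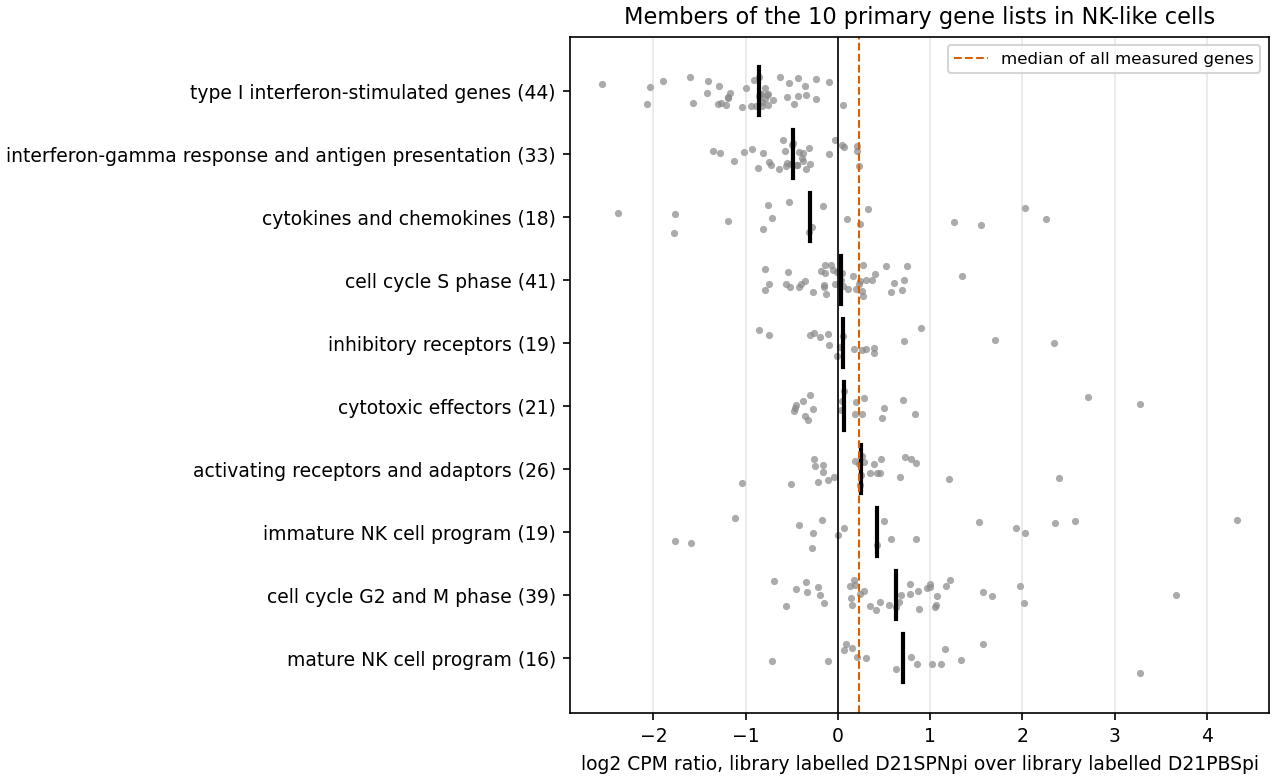
Log2 ratio of CPM, library labelled D21SPNpi over library labelled D21PBSpi (horizontal axis), for each measured member (points, spread vertically at random for display) of the 10 primary gene lists, with the list median as a black bar and the number measured in brackets. The dashed line is the median of all measured genes, 0.23. The type I interferon list has a median of -0.85 with 40 of 44 members at a ratio of 0.8 or less. The cytotoxic, S phase and inhibitory receptor medians lie between 0 and the dashed line and turn negative under TMM scaling.

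Genes of the mature NK cell program were higher in the library labelled D21SPNpi, by the labels. Of 16 measured, 9 were higher and 1 lower, and the median log2 ratio was 0.71 (0.48 relative to all genes), above all 10000 random lists. Cma1 and S1pr5, a receptor that lets NK cells leave tissues (2.98-fold, 2.69 to 3.31), were the highest. Both were high mainly in cluster 5 of the library labelled D21SPNpi. S1pr5 stood at 129 CPM there, but at 2.48 CPM in cluster 4 and 5.98 CPM in cluster 3 of that library. Cma1 stood at 497 CPM, 29.7 CPM and 8.18 CPM in the same clusters. In cluster 0 labelled D21PBSpi S1pr5 stood at 52.4 CPM and Cma1 at 72.6 CPM. Prdm1, which encodes the regulator Blimp-1, was the lowest at 0.612 (0.565 to 0.662), followed by Ly6c2 at 0.930 (0.902 to 0.959). Klrg1, a receptor of mature NK cells, stood at 141 CPM against 114 CPM (1.24, 1.16 to 1.32), with a UMI in 26.3% against 22.9% of thinned cells and 37.2% against 37.9% unthinned. In cluster 5 labelled D21SPNpi Klrg1 (191 CPM), Ly6c2 (734 CPM) and Prdm1 (40.5 CPM) were below cluster 0 labelled D21PBSpi (201, 1111 and 150 CPM). Members of the immature program went both ways, 10 of 19 higher and 4 lower (8 and 7 under TMM). Their median was 0.42 (0.20 relative to all genes, percentile 97.0), but their summed CPM was lower, 2135 against 3747, mainly through Xcl1. Tcf7, a transcription factor gene of early and memory lymphocytes, was 5.94-fold higher (4.47 to 8.01) and the chemokine receptor gene Cxcr6 lower at 0.331 (0.215 to 0.495).

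Among receptors the differences were spread over individual genes. Of 26 activating receptors and adaptors, 11 were higher and 2 lower in the library labelled D21SPNpi, against 6 and 8 under TMM, and the median log2 ratio was 0.25 (0.03 relative to all genes, percentile 98.4). Ncr1 (NKp46) stood at 609 CPM against 866 CPM (ratio 0.704, 0.685 to 0.723) and Slamf7 at 0.485 (0.463 to 0.508). The Fc receptor gene Fcgr3 (CD16), which mediates killing of antibody-coated cells, was 5.28-fold higher (4.17 to 6.74), at only 26.5 CPM against 5.02 CPM. Crtam was 2.31-fold higher (1.87 to 2.86), at 18.2 CPM against 7.87 CPM, and Klrb1c was nearly equal at 1.2 (1.16 to 1.23). An Ncr1 UMI was found in 70.2% of thinned cells labelled D21SPNpi and 78.8% of those labelled D21PBSpi (78.7% and 89.7% unthinned). Of 19 inhibitory receptors 6 were higher and 2 lower (4 and 7 under TMM), with a median of 0.06 (-0.17 relative to all genes and -0.19 under TMM, percentile 33.8). Lair1 was 5.08-fold higher (3.77 to 6.96), at 15.9 CPM against 3.14 CPM, and Cd96 3.24-fold (2.57 to 4.11), at 19.1 CPM against 5.88 CPM. Lilrb4a (0.553, 0.516 to 0.593) and Lag3 (0.594, 0.494 to 0.713) were lower. The early activation gene Cd69 stood at 101 CPM against 226 CPM (ratio 0.448, 0.421 to 0.476), with a UMI in 15.1% against 32.1% of thinned cells and 24.0% against 52.1% unthinned.

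Mki67, a gene of cycling cells, was found in few cells of either library. It had 43 UMIs labelled D21SPNpi and 28 labelled D21PBSpi, and a UMI in 0.25% of thinned cells in each (6 of 2403 and 6 of 2399), or 0.525% and 0.563% unthinned. Without cells over 2.5 times the median UMIs, an alternative chosen after the values were seen, its ratio of 1.95 (1.18 to 3.26) became 0.777. Of 41 S phase genes 9 were higher and 9 lower (6 and 16 under TMM), with a median log2 ratio of 0.03 (-0.20 relative to all genes, -0.22 under TMM and -0.01 with a total without mitochondrial and ribosomal protein genes, percentile 0.41). Atad2 (1.62, 1.44 to 1.82) was among the higher members and Uhrf1 (0.578, 0.414 to 0.799) and Cdca7 (0.580, 0.382 to 0.866) were the lowest. Of 39 G2 and M phase genes 24 were higher and 5 lower (20 and 8 under TMM), with a median of 0.62 (0.40 relative to all genes, percentile 99.8). That median was 0.24 among members with at least 100 UMIs. Among members with at least 100 UMIs, Cks2 (2.32, 2.08 to 2.59) and Ndc80 (2.11, 1.65 to 2.69) were the highest, and Cks1b (0.618, 0.486 to 0.781) and Ckap5 (0.730, 0.617 to 0.861) the lowest.

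Cells of cluster 3, the only NK-like cluster with at least 100 cells of each library, did not show the interferon difference over the type I list as a whole. In it the type I interferon list had a median log2 ratio of 0.15 over 40 measured members, where all 8876 measured genes had a median of 0.09, and the same 40 members had a median of -0.85 over all NK-like cells. There 15 members were higher and 3 lower, and Bst2 was still lower at 0.745 (0.683 to 0.813), as was Socs1 of the interferon-gamma list by a smaller margin at 0.869 (0.765 to 0.985). The interferon-gamma list stood at 0.27 (0.18 relative to the genes of that cluster, percentile 99.9), with 13 of 33 members higher and 1 lower. The mature program had a median of 0.03 in cluster 3, the cytotoxic list 0.15, the cytokine list 0.20, the activating receptors 0.11, the inhibitory receptors -0.16, the immature program -0.16, the S phase list -0.21 and the G2 and M phase list -0.01. Gzmb stood at 21635 CPM labelled D21SPNpi against 18936 CPM labelled D21PBSpi (ratio 1.14, 1.13 to 1.15), and Prf1 at 1573 CPM against 1778 CPM (0.885, 0.852 to 0.918). Ccl5 was 1.86-fold higher (1.83 to 1.90) in the cells labelled D21SPNpi, and Ncr1 was lower at 0.628 (0.567 to 0.695), both as over all NK-like cells. Other genes turned in cluster 3, with Lag3 at 1.63 (1.18 to 2.25), Lilrb4a at 1.21 (1.09 to 1.35), Slamf7 at 1.11 (1.00 to 1.23) and Klrg1 at 0.697 (0.565 to 0.858), while Xcl1 and Cd69 were both near equal at 1.06. The clusters were built from expression, so cells within one were already alike.

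**Figure D3:**
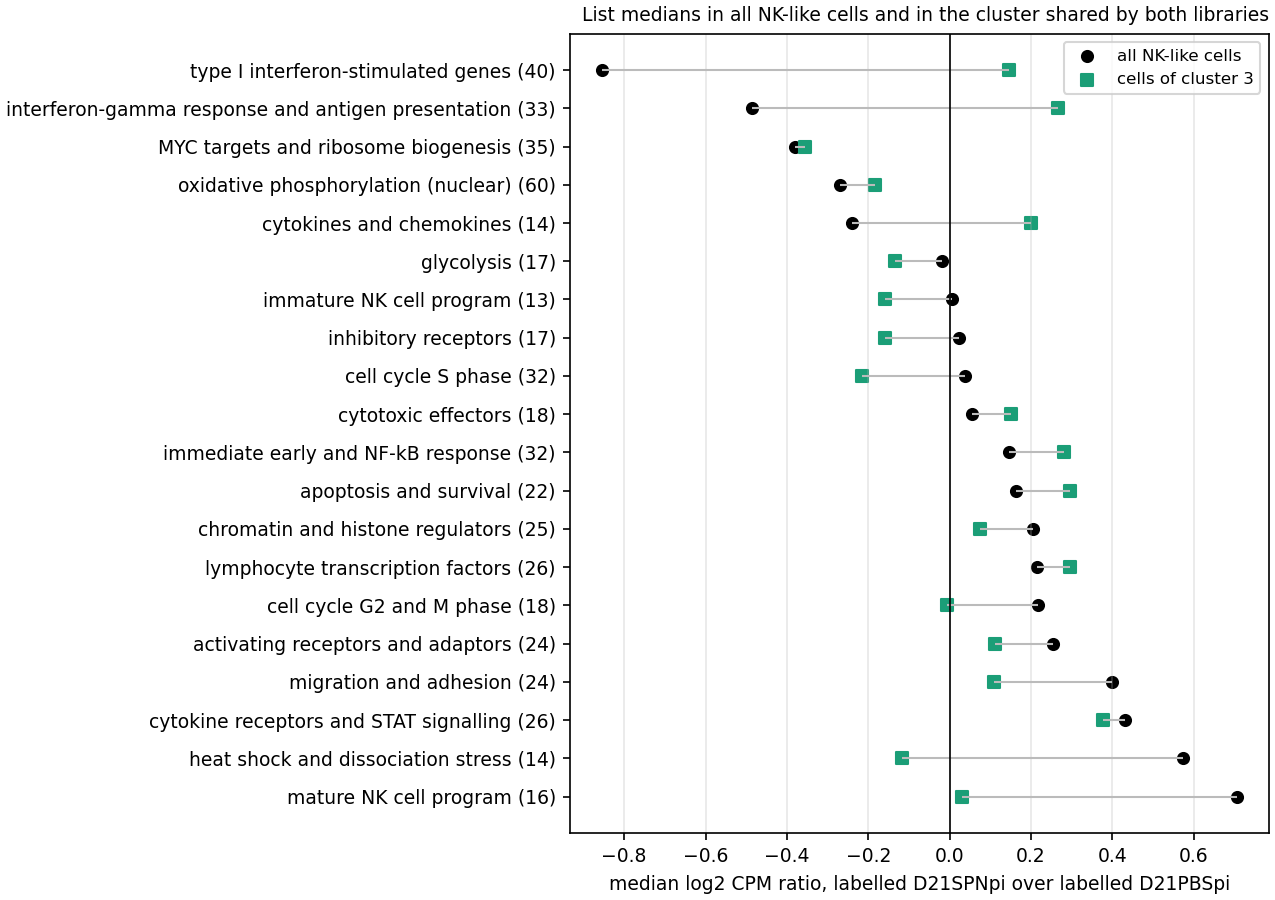
Median log2 ratio of CPM, labelled D21SPNpi over labelled D21PBSpi (horizontal axis), of 20 gene lists (rows, measured members in brackets) over all NK-like cells (circles) and over the 462 and 546 cells of cluster 3 (squares), for the same members. The median of all genes is 0.23 over all NK-like cells and 0.09 in cluster 3, so signs of medians near 0 depend on the scaling. The type I interferon list moves from -0.85 to 0.15, and the MYC target list stays at -0.38 and -0.36.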

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

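No paired analysis was possible because each group has 1 library. Of the alternatives, the removal of cells with epithelial or fibroblast markers and of cells over 2.5 times the median UMIs were chosen only after the result was seen. Under TMM scaling, which moved the median of all genes from 0.23 to -0.02, the type I interferon list had a median log2 ratio (labelled D21SPNpi over labelled D21PBSpi) of -1.10, the interferon-gamma list -0.73, S phase -0.22, inhibitory receptors -0.19, immediate early genes -0.12, cytokine receptors 0.19, oxidative phosphorylation -0.52, MYC targets -0.63 and apoptosis genes -0.086. With at least 100 UMIs per gene the G2 and M phase list had 0.24. Those 10 medians left the bootstrap interval of their list, and 230 others stayed within it. TMM lowered every list, though, and within those intervals it also took the cytotoxic median to -0.18 and that of chromatin regulators to -0.04, below 0. Of the alternative CPM ratios 824 stayed within their counting interval and 191 left it. These ratios were computed only for genes that the naming rule selects, which mostly takes the ends of the ratios, and other genes were not followed. Among the selected genes with a ratio of 0.8 or less, or of its inverse or more, only that of Mki67 crossed 1 in these alternatives. It stood at 0.777 without cells over 2.5 times the median UMIs. Ratios nearer to 1 crossed it as well, that of Ifng (1.07) at 0.901 under TMM, 0.993 with equal weight per cell and 0.873 with the gate. Of the alternative shares of cells with a UMI 10 stayed within theirs and 42 left it. The share of cells called NK-like, labelled D21PBSpi then D21SPNpi, was 100% and 100% at resolution 0.3, with doublets kept and with the stricter filter, 85.7% and 95.2% at resolution 1.2, and 77.8% and 89.8% with the looser filter. The unthinned gate on Ncr1 or Klrb1c without Cd3d, Cd3e, Cd3g, Cd79a or Lyz2 gave the opposite order, 91.0% and 86.7%. At resolution 0.6 no cluster was led by S or G2 and M phase genes, so the alternative without such clusters gave no value. At resolution 1.2, and with the stricter filter, 1 cluster had the S phase genes Mcm3, Mcm5 and Mcm7 among its 10 leading genes, and no values were computed without it.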

Other observations

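Of the tests in this part, those of exchanged sample labels and of droplets with free RNA were chosen only after the result was seen. Further gene lists gave the following ratios of the library labelled D21SPNpi over the library labelled D21PBSpi, which would all invert if the file names are right about the groups. Members called highest or lowest are so among those with at least 100 UMIs. Transcripts of ribosome building and growth were lower. Of 35 MYC targets and ribosome biogenesis genes 22 were lower and 0 higher (31 and 0 under TMM), with a median log2 ratio of -0.38 (-0.61 relative to all genes), below all 10000 random lists. Srm, an enzyme of polyamine synthesis (0.510, 0.463 to 0.562), and the nucleotide kinase gene Nme1 (0.549, 0.529 to 0.569) were the lowest members, and the amino acid transporter gene Slc3a2 the highest at 1.11. In cluster 3 the list median was -0.36. Of 60 nuclear genes of oxidative phosphorylation 23 were lower and 1 higher (47 and 0 under TMM). Their median was -0.27 (-0.50 relative to all genes), again below every random list, and -0.18 in cluster 3. The random lists matched on expression had a median of -0.04. Cycs (cytochrome c) was the lowest at 0.564, then Ndufb2 at 0.647, and Sdhd the highest at 1.32. The 18 glycolysis genes went both ways, 5 at each end (3 higher and 7 lower under TMM), with a median of 0.00 (-0.23 relative to all genes, -0.25 under TMM, percentile 22). In cluster 3 their median was -0.13. The glucose transporter gene Slc2a3 stood at 1.86, the lactate transporter gene Slc16a3 at 1.61 and the phosphofructokinase gene Pfkp at 0.703.

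Stress and signalling lists leaned the other way in part. Of 14 heat shock genes 8 were higher and 1 lower (7 and 4 under TMM), with a median of 0.57 (0.35 relative to all genes), above all random lists, but -0.12 in cluster 3. Hspa1b (2.55) and Hspa1a (2.20), near-identical copies of a chaperone gene, were the highest, and the endoplasmic reticulum chaperone gene Hspa5 was the lowest at 0.642. Tissue dissociation also induces these genes, and its length per library is not given in the sources used here. Of 27 cytokine receptor and STAT genes 16 were higher and 3 lower (8 and 6 under TMM), with a median of 0.44 (0.21 relative to all genes, percentile 99.9) and 0.38 in cluster 3. Il21r (3.23) and Il7r (2.89) were the highest, and Il12rb1, a receptor chain for interleukin 12 (0.298, 0.258 to 0.343), and Cish (0.642) the lowest. Of 29 migration and adhesion genes 17 were higher and 3 lower (14 and 4 under TMM), with a median of 0.42 (0.20 relative to all genes, percentile 99.9), and S1pr1 at 8.76. In cluster 3 that median was 0.11, with 6 of 24 measured members higher and 6 lower. The 36 immediate early and NF-kB genes had 11 higher and 6 lower (9 and 14 under TMM), with a median of 0.13 (-0.10 relative to all genes, -0.12 under TMM, percentile 89.5). In cluster 3 their median was 0.28, with 14 of 32 measured members higher and 1 lower. Nr4a1 stood at 2.40 (2.27 to 2.53), Zfp36l1 at 2.19, Ier3 at 0.367 and Atf3 at 0.376. In cluster 3 Ier3 was still lower at 0.706, but Atf3 was not, at 1.32 (0.875 to 1.99). Of 32 lymphocyte transcription factors 15 were higher and 4 lower (12 and 10 under TMM), with a median of 0.25 (0.02 relative to all genes, 0.00 under TMM, percentile 94.2). Bach2 was 5.92-fold higher, Id3 stood at 0.372 and Zbtb32 at 0.536. The 22 apoptosis genes had 9 higher and 6 lower (4 and 6 under TMM), with a median of 0.16 (-0.07 relative to all genes, -0.09 under TMM, percentile 72.9), Bcl2a1d at 2.48 and Gimap4 at 0.641. The 25 chromatin regulators had 9 higher and 1 lower (3 and 8 under TMM), with a median of 0.21 (-0.02 relative to all genes, -0.04 under TMM, percentile 74.0), Tet2 at 2.02, Kmt2d at 1.80 and Smarcb1 at 0.642. In cluster 3 the transcription factors had a median of 0.30, the apoptosis genes 0.30 and the chromatin regulators 0.07. All genes of that cluster had 0.09.

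The lower interferon-stimulated genes of the library labelled D21SPNpi were weighed against technical causes. Among NK-like cells of 4500 to 6500 UMIs (953 and 1060 cells) the type I median was -1.71 (bootstrap over members -1.83 to -1.51). CPM is already scaled to the summed UMIs, so a range of like depth could hardly have removed the difference. The range can also change the mix of clusters. Median UMIs labelled D21PBSpi were 5341 in cluster 0, 7973.5 in cluster 1 and 7131.5 in cluster 3. Those labelled D21SPNpi were 4888 in cluster 5 and 3991 in cluster 4. No conclusion on fewer UMIs per cell as the cause is drawn. With clusters made without the genes of both interferon lists, the NK-like cluster shared by 506 and 494 cells had a median of 0.15 (bootstrap 0.08 to 0.31). The list was thus not lower in those cells. The other NK-like clusters came nearly all from 1 library, and cells grouped by expression are already alike. Whether a shift of the same size affected every cell of 1 library therefore cannot be decided. Exchanged sample labels cannot be told apart from the labels as given, because each group has 1 library and the median of -0.85 would only change sign. The first infection of the donors, recipient and handling of each library all stay open, so a difference between naive and memory cells may be the source but was not tested.

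The low-UMI cells of the library labelled D21PBSpi differed in makeup from its NK-like cells. Malat1, a nuclear RNA, was 3.41-fold higher in them (3.39 to 3.44), the cytoskeletal gene Actb lower at 0.541 (0.526 to 0.556), and mitochondrial genes held 5.56% against 1.93% of UMIs. Of the other genes looked at, Neat1 was 3.99-fold and Xist 3.12-fold higher, and Tmsb4x (0.396), Eef1a1 (0.432) and Ccl5 (0.508) were lower. Prf1 was 2.10-fold, Gzma 1.70-fold, Gzmb 1.37-fold and B2m 1.35-fold higher, and Ifng was near equal at 0.985. Damaged cells that lost cytoplasmic RNA are a candidate explanation for Malat1 and Actb. Whether such a loss would leave Prf1, Gzma, Gzmb and B2m higher was not tested, and no biological explanation was tested. Droplets with free RNA cannot be told apart from damaged cells, because the ribosomal protein share of 7.15% against 22.1% (ratio 0.324) has no measured profile of free RNA to be set against.

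After thinning, the top 10% of cells of the library labelled D21SPNpi held 78.6% of its Ifng UMIs, against 55.0% in the library labelled D21PBSpi. Without cells over 1.5 times the median UMIs the share labelled D21SPNpi was 80.0%, so the concentration was also present without those cells. Thinning had already set all cells to the same number of UMIs, so leaving out deep cells could hardly have lowered the share. No conclusion on doublets or very deep cells as the cause is drawn. In the library labelled D21SPNpi clusters 3 and 4, with 20.5% and 11.3% of its NK-like cells, held 68.5% and 24.6% of its Ifng UMIs. Cluster 5, with 66.0% of the cells, held 5.72%. In the library labelled D21PBSpi cluster 3, with 18.6% of the cells, held 54.2%. A subset of strong interferon-gamma producers may explain this, but Ifng is among the leading genes of cluster 3, so the clusters are no independent test, and a role of the donors' first infection was not tested.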
